A study of Mus musculus with 48 samples.

How the data were processed

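RNA of epidermal stem cells (EpSCs) from 48 female mice was measured on 1-colour Affymetrix arrays: 6 times of day, young and aged mice, 4 mice in each of the groups. Per the labels, RNA was extracted with TRizol, amplified from 25 ng of total RNA with the WTA2 kit in 17 cycles, and 8 µg of cDNA was fragmented and labelled with biotin. The deposited values are log2 probe set summaries that the authors made with RMA, which adjusts background, aligns the distributions of the arrays and summarises the probes. The version of RMA, and whether all arrays were normalised together, are not given in the sources used here. Had the ages been normalised apart, the comparison of levels would be affected. Dates of harvest and hybridisation, the light schedule and the purity of the cells are also not given in the sources used here.

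The file holds 45141 probe sets. Of these 28898 carry exactly 1 gene symbol in the probe table, 551 carry several and 15692 are not in it. For each of 17097 genes the probe set with the highest mean over all arrays was used, and the genes in the lowest 25% of these means (a mean log2 under 3.96) were left out as dim, which leaves 12823 genes. Coordinates are from GRCm38. Values were used as deposited, with no further normalisation. Array weights, the 3' minus 5' signals of actin and Gapdh, hybridisation controls and the background of high-GC probes were recorded per array.

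The groups, tests, gene lists and most alternatives were set before the data were examined. Genes were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes). The model held a mean for each age and, within each age, a cosine and a sine of clock time with a period of 24 h. F tests of cosine and sine asked whether a gene was rhythmic in young, in aged, or differed between the ages, and the contrast of the means gave the level of aged minus young. P values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. The amplitude is that of the fitted cosine on the log2 scale, from the mean to the peak, and the peak time is when the cosine is highest. Errors of amplitudes, peaks and differences are standard errors of the fit.

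There were 33 gene lists, 20 of pathways and 13 of cell types, with 577 genes, of which 521 are in the probe table and 465 were tested. The pathway lists were core clock, S phase and replication, G2 and mitosis, DNA repair, p53 targets, oxidative phosphorylation, glycolysis, Nrf2 targets and antioxidants, heat shock chaperones, unfolded protein response, autophagy and lysosome, ribosome biogenesis, cholesterol synthesis, glucocorticoid-induced genes, immediate early genes, interferon-stimulated genes, stressed keratinocyte and inflammation, basement membrane and adhesion, Notch and Wnt. The cell type lists were basal and suprabasal keratinocyte, hair follicle bulge, upper follicle and sebaceous gland, fibroblast, endothelium, Langerhans and myeloid cell, T cell, melanocyte, Merkel cell, adipocyte, skeletal muscle and red blood cell. Level by list was tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry, each 2-sided and adjusted over the lists. Rhythm by list was tested with a 1-sided Fisher's exact test of the share of rhythmic members against the other tested genes. The list score, the mean of the members after each was centred and divided by its SD, was fitted with the same cosine. Its p came from 100000 permutations of the times within each age or, for the difference, of the ages within each time (smallest possible p 1e-05).

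Named genes follow a rule: every measured core clock gene, the 10 rhythmic genes with the largest amplitude per age, the 5 smallest p of the difference where none passed, the 10 largest rises and falls in level, and up to 3 members of each list with the smallest p of the comparison described. Predicted genes and clone names were passed over. Genes outside the rule are named as such.

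The alternatives were: no filter on dim genes, or the lower 50% left out; the mean of all probe sets; arrays centred on their median; cyclic loess; array weights; eBayes with trend and robust; the replicate number as a block; scores of 5 cell type lists as covariates (cell mixture); time of day as a factor; each age fitted alone; a rank test of the JTK type; a peak at least 1.2 times the trough; a change of at least 1.5 times; and each array left out in turn. Removal of the 4 arrays of lowest weight and technical measures as covariates were chosen after seeing the data. GEO's labels number the mice of each group 1 to 4. Residuals of arrays with the same number had a mean correlation of -0.0007 (0.0009 for different numbers), so mice were treated as independent and the replicate block was tried as an alternative.

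The gene tests were tested on simulated data: normal noise around the mean of each gene with its residual SD, independent between genes, and known changes added to 50 genes per class. Arrays that stand apart as a whole were not simulated. Neither were daily courses other than a cosine, as the SD was that around the group means. At an amplitude of 0.6 the limma fit found 50 of 50 rhythms in young and 49 of 50 in both ages. At 0.3 it found 42 of 50 in young, with 8 of 12623 unchanged genes called. A rhythm in young alone was called as a difference in 25 of 50 genes at 0.3 and 43 of 50 at 0.6. A change in level of 0.5 was found with its sign in 50 of 50 genes, with 4 unchanged genes called, and the peak time had a median error of 0.336 h.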

Results

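Epidermal stem cells (EpSCs) were collected from the skin of wild-type female C57B6/J mice through 1 day, and their RNA was measured on 1-colour Affymetrix arrays. Young mice were 8 weeks old and aged mice 102 to 116 weeks old. Each age was sampled at ZT0, ZT4, ZT8, ZT12, ZT16 and ZT20, where ZT0 is by convention the time the lights come on. There were 4 mice per age and time, which gives 24 arrays per age and 48 in all. Array medians lay between 4.78 and 5.04 on the log2 scale, and the correlation between arrays had a median of 0.989 (lowest 0.963). The background of high-GC probes was 6.23 ± 0.34 in young and 6.05 ± 0.36 in aged arrays (SD, n = 24 each; permutation test, adjusted p = 0.171). Hybridisation controls and the 3' minus 5' signals of actin and Gapdh also did not pass the test between the ages (adjusted p = 0.676, 0.275 and 0.171). For arrays the number of mice limits the precision.

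The series compares daily expression in young and aged EpSCs, so the core clock was examined before other genes. The clock ran with large amplitudes and like peak times at both ages. Dbp, an output transcription factor of the clock (chromosome 7, 45705100 to 45710203 in GRCm38), peaked at ZT10.27 ± 0.22 in young and ZT10.69 ± 0.23 in aged cells (SE, n = 24 arrays each), with a peak 14.4 and 11.6 times its trough. The repressor Per3 peaked at ZT12.92 and ZT12.96, Tef at ZT11.63 and ZT12.06, Nr1d2 at ZT9.91 and ZT9.94 and Ciart at ZT12.43 and ZT11.74. In the opposite phase, the activator Npas2 peaked at ZT23.27 ± 0.36 in young and ZT23.62 ± 0.52 in aged cells.

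Of the 16 measured members of the core clock list, 9 were rhythmic in young and 10 in aged cells, and 12 and 12 were with p adjusted over the list alone (limma F test). The list score, the mean of the standardised members per array, had a 24 h amplitude of 0.50 ± 0.06 in young (peak ZT12.8) and 0.39 ± 0.06 in aged cells (peak ZT12.65), with an adjusted permutation p of 0.00033 in each. Dbp had a log2 amplitude of 1.92 ± 0.11 in young and 1.77 ± 0.11 in aged cells (SE; adjusted p = 1.03e-17 and 5.71e-16). Per2, a repressor of the clock (chromosome 1, 91415977 to 91459351), had an amplitude of 1.16 ± 0.09 in young and 0.64 ± 0.09 in aged cells (adjusted p = 4.73e-13 and 2.65e-05). The amplitude difference for Per2 was -0.52 (95% confidence interval -0.77 to -0.27), but the test of its whole rhythm did not pass over all genes (adjusted p = 0.235). Intervals of Per1 (-0.587 to -0.0836), Npas2 (-0.346 to -0.0265) and Nr1d2 (-0.455 to -0.0123) were also negative throughout. Those of the other clock genes spanned both signs. The whole rhythms of these 3 genes did not pass either (limma F test, adjusted p from 0.606 to 0.77). Per1 was rhythmic in young cells (amplitude 0.54, adjusted p = 3.19e-04) and had an amplitude of 0.20 in aged cells (adjusted p = 0.542), and the difference between the ages did not pass (adjusted p = 0.606). With time as a factor in place of the cosine, the daily course differed between the ages in 1 of the 16 clock genes. Arntl, the partner of Clock, was rhythmic in aged cells (0.72, adjusted p = 0.0188) and had an amplitude of 0.42 in young cells (adjusted p = 0.189). With cell mixture covariates the aged Arntl rhythm did not pass (adjusted p = 0.133), and with the mean of all probe sets the young one did (adjusted p = 0.002). Another Arntl probe set, of lower mean, gave the reverse order of amplitudes. It had 0.80 in young and 0.52 in aged cells (limma, unadjusted p = 1.41e-08 and 7.92e-05). Cry1 was rhythmic at both ages (0.79 and 0.69), while Cry2 had adjusted p of 0.0518 in young and 0.00119 in aged cells, with no difference past the test (adjusted p = 0.869). The young Cry2 rhythm passed in 12 of 60 alternatives (adjusted p from 0.0104 to 0.11). Clock, Rora, Hlf, Nfil3 and Bhlhe40 had adjusted p between 0.0523 and 0.911 at both ages. The lowest was that of Hlf in aged cells, whose rhythm passed in 18 of 60 alternatives (adjusted p from 0.00643 to 0.169).

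**Figure D1:**
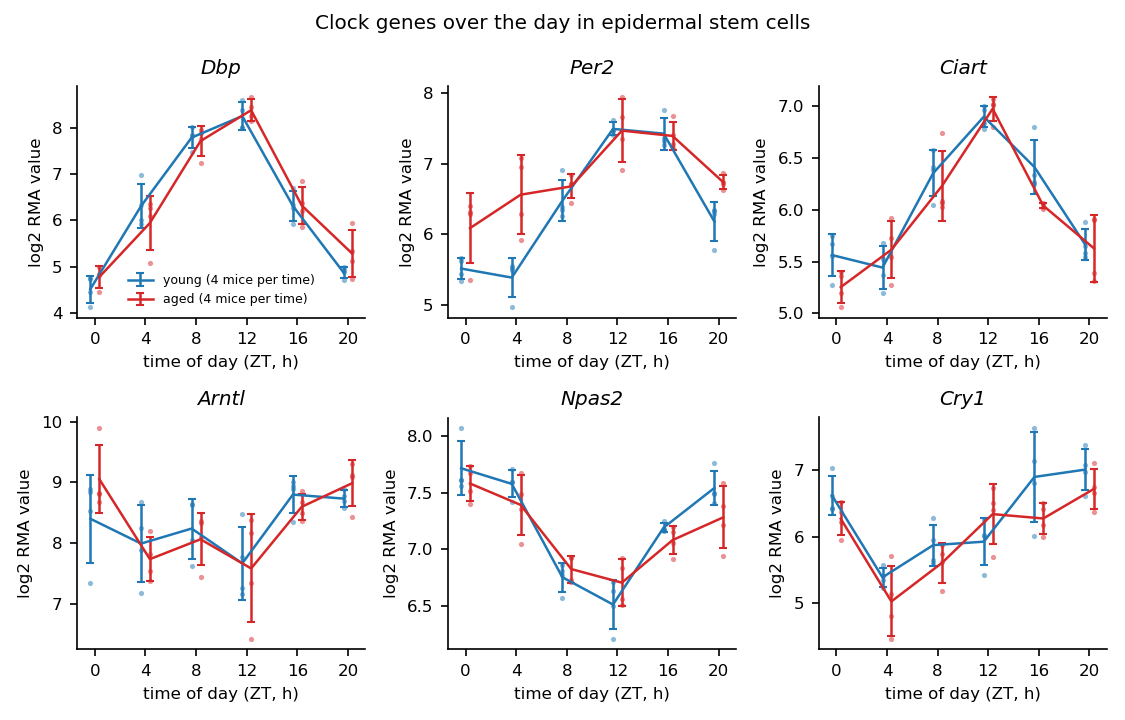
Log2 expression of Dbp, Per2, Ciart, Arntl, Npas2 and Cry1 against ZT (h) in young and aged EpSCs; points are single mice, lines join group means and bars are 1 SD (n = 4). Dbp, Per2 and Ciart are high near ZT12 at both ages and Npas2 near ZT0, and the Per2 curve has a fitted amplitude of 1.16 in young and 0.64 in aged cells.

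Beyond the clock, the rhythmic genes of large amplitude had varied functions. Ttc9 was at its peak at ZT23.7 in young and ZT23.22 in aged cells, at 7.40 and 3.69 times its trough. Dab1, a signalling adaptor, peaked at ZT2.00 and ZT3.49 (amplitude 0.90 and 0.47), and Mthfd1l, a mitochondrial folate enzyme, at ZT13.26 and ZT13.61 (0.62 and 0.77). All 3 were rhythmic at both ages. In young cells the largest amplitudes also belonged to Fkbp5, Tsc22d3 and Pdk4, which glucocorticoids induce.

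In the limma F test of a 24 h cosine, 804 of 12823 genes were rhythmic in young and 174 in aged cells, with 2657 and 1458 at an unadjusted p under 0.05. There were 104 genes rhythmic at both ages, against 10.9 expected of independent lists, with a median shift in peak time of 0.867 h. The shift was under 2 h for 90 of them, and 58 had the larger amplitude in young cells. The fit uses the same estimate of the spread per gene for both ages, so the lists are not fully independent. In young cells 295 genes peaked in the 4 h window around ZT0 and 237 in that around ZT4, together with 116 around ZT12. The first 2 counts were 479 and 385 without young ZT0 replicate 2. In aged cells 62 genes peaked around ZT12, 39 around ZT4 and 15 around ZT0. The median amplitude was 0.30 in young and 0.35 in aged rhythmic genes, and the residual SD of each age fitted alone was 0.206 and 0.192. The aged count was 314 without aged ZT12 replicate 1. Without the 4 arrays of lowest weight, chosen after seeing the data, 582 genes were rhythmic in young and 438 in aged cells, while array weights, which count the same arrays less, gave 1772 and 378. With cell mixture covariates the counts were 1154 and 86. The size of the gap thus depends on the treatment of these arrays and on the covariates. Without those 4 arrays 223 young genes peaked around ZT0 and 143 around ZT4, and 81 aged genes around ZT0, 100 around ZT4 and 150 around ZT12. Without aged ZT12 replicate 1 alone 54 aged genes peaked around ZT0, 60 around ZT4 and 123 around ZT12.

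**Figure D2:**
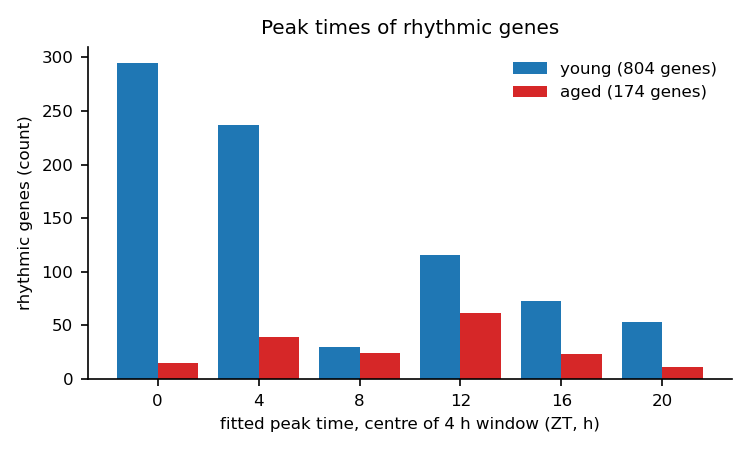
Number of rhythmic genes (vertical axis) by fitted peak time in windows of 4 h (horizontal axis, ZT in h) in young and aged EpSCs. Young counts are highest around ZT0 (295) and ZT4 (237), and the aged count is highest around ZT12 (62).

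In young cells the fitted 24 h peak of S phase genes came earlier in the day than that of genes of G2 and mitosis. The score of S phase genes, which replicate DNA, had its fitted peak near ZT13.3 at both ages. That of G2 and mitosis had it near ZT22.8 in young cells. The young S phase course was not a single cosine wave. Its score was 1.03 ± 0.45 at ZT12, -0.43 ± 0.17 at ZT16 and 0.31 ± 0.24 at ZT20 (SD, n = 4). The young G2 and mitosis score was highest at ZT20 too (1.00 ± 0.25), so the order is that of the fitted peaks. Of 24 measured S phase genes, 10 were rhythmic in young and 17 in aged cells (17 and 24 with p adjusted over the list alone). Chaf1b peaked at ZT12.52 and ZT13.51 (amplitude 0.37 and 0.41), Mcm3 of the replicative helicase at ZT11.88 and ZT12.54 (0.51 and 0.53) and E2f1 at ZT13.41 and ZT13.48 (0.23 and 0.41). Of 23 genes of G2 and mitosis, 19 were rhythmic in young and 1 in aged cells (22 and 7 with p adjusted over the list alone), among them the motor Kif11 (0.71, peak ZT21.31 in young) and cyclin Ccnb2 (0.61, peak ZT0.72). The 1 in aged cells was Nusap1 (0.48, adjusted p = 0.0426), which passed in 41 of its 60 alternatives (adjusted p up to 0.127). By the rank test 11 of the 23 were rhythmic in young and 0 in aged cells, where limma gave 12 with an unadjusted p under 0.05 and the fit with time as a factor 4.

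The share of rhythmic genes among S phase genes exceeded that of other genes at both ages (1-sided Fisher's exact test, adjusted p = 8.55e-06 in young and 8.51e-26 in aged), and that of the G2 and mitosis list in young cells (2.64e-18). Fisher's test counts genes as independent, but the members are correlated (estimated correlation 0.48 for S phase and 0.63 for G2 and mitosis). These p values are thus too small, and the scores that follow have mice as replicates. The S phase score had an amplitude of 0.61 ± 0.17 in young and 0.97 ± 0.14 in aged cells (SE, n = 24; adjusted permutation p = 0.0389 and 0.00033). The G2 and mitosis score had 0.98 ± 0.17 and 0.41 ± 0.20 (adjusted permutation p = 0.00088 and 0.366). Neither score differed between the ages past the threshold (permutation of ages within time, adjusted p = 0.432 and 0.422). The S phase count in young cells was 6 without young ZT0 replicate 4, and that in aged cells was 11 without aged ZT0 replicate 3 and 10 without aged ZT12 replicate 2. The young S phase score did not pass without any 1 of the young arrays of ZT4 and ZT12, of ZT0 replicates 1, 2 and 4 or of ZT8 replicates 2 and 4 (adjusted p between 0.0517 and 0.082). The aged count of G2 and mitosis genes reached 4 without aged ZT4 replicate 1.

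Genes induced by glucocorticoids followed a 24 h rhythm in young cells that the aged cells did not show. In young cells Fkbp5, a co-chaperone of the glucocorticoid receptor, peaked at ZT12.48 with a peak 7.38 times its trough, Tsc22d3 (GILZ) at ZT12.59 (5.15 times) and Pdk4, a kinase that restrains pyruvate use, at ZT12.73 (4.47 times). Their 24 h amplitudes were 1.44 ± 0.29, 1.18 ± 0.21 and 1.08 ± 0.23 in young cells (SE; adjusted p = 0.00338, 7.72e-04 and 0.00579) and 0.39, 0.54 and 0.25 in aged cells (0.83, 0.439 and 0.881). The aged cells did vary between times. Fkbp5 was at 9.47 ± 0.90 at ZT4 and 9.75 ± 0.18 at ZT16 (log2, SD, n = 4), but at 6.96 ± 0.80 at ZT0 and 7.63 ± 1.0 at ZT8.

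Of the 14 measured members, 6 were rhythmic in young cells (9 with p adjusted over the list alone) and 0 in aged cells by limma, where 2 had an unadjusted p under 0.05. The rank test called 4 in young and 0 in aged cells, while with time as a factor 9 varied at each age. The score had a 24 h amplitude of 0.73 ± 0.12 in young (peak ZT12.54) and 0.10 ± 0.16 in aged cells (adjusted permutation p = 0.00088 and 0.894). It was the 1 list of 33 whose score rhythm differed between the ages (permutation p = 0.00033, adjusted p = 0.0109), and 5 members differed with p adjusted over the list alone. The adjusted p of this difference was 0.0759 without young ZT0 replicate 3 and 0.0528 without young ZT16 replicate 1 or replicate 4. It was also 0.0528 with arrays centred on their median, 0.109 with technical covariates and 0.126 without the 4 arrays of lowest weight.

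**Figure D3:**
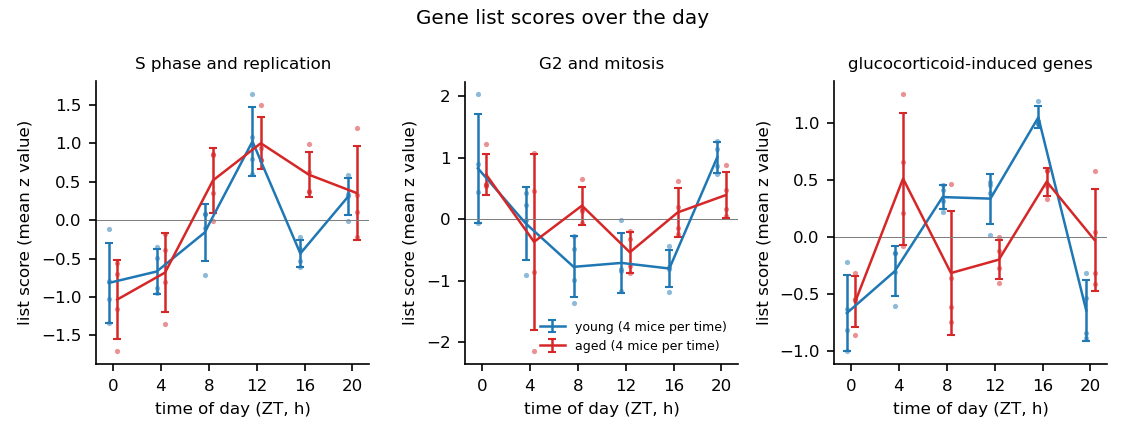
Score of the S phase, G2 and mitosis and glucocorticoid lists (vertical axis, mean of standardised log2 values) against ZT (h); points are mice and lines join the means of 4 mice, for young and aged EpSCs. The fitted 24 h amplitude of the glucocorticoid score is 0.73 in young and 0.10 in aged cells.

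Other lists with a daily rhythm in their score were fewer. The ribosome biogenesis score peaked at ZT13.9 in young cells (amplitude 0.61 ± 0.13, adjusted permutation p = 0.00726), with 2 of 18 members rhythmic by themselves (0 without young ZT16 replicate 3 and 5 without aged ZT12 replicate 1). The basement membrane score peaked at ZT7.35 (0.30 ± 0.07, adjusted permutation p = 0.0177, and 0.065 after cyclic loess), with 1 of 17 (2 without young ZT4 replicate 3). In aged cells the Wnt pathway score peaked at ZT7.03, with 1 of 17 members rhythmic, and 0 without aged ZT0 replicate 3 (0.32 ± 0.07, adjusted permutation p = 0.00759, but 0.0801 with cell mixture covariates and 0.0694 with more of the dim genes left out). In young cells the Wnt score had an adjusted permutation p of 0.0825, with the receptors Fzd10 (amplitude 0.42) and Lgr6 (0.35) rhythmic. The DNA repair score peaked at ZT12.07 in aged cells, where 3 of 27 members were rhythmic, and 2 without aged ZT0 replicate 3 (0.40 ± 0.10, adjusted permutation p = 0.0203), and did not pass without aged ZT0 replicate 1 (0.0602), replicate 3 (0.066) or replicate 4 (0.0536). In none of these 4 lists did the share of rhythmic members exceed that of other genes at either age (Fisher's exact test, adjusted p from 0.0622 to 1). None of these scores differed between the ages (adjusted p from 0.401 to 0.988). In the remaining lists no score passed; the smallest adjusted permutation p was 0.0846 in young, for basal keratinocyte and upper follicle markers, and 0.171 in aged cells, for the unfolded protein response. Single rhythmic members of those lists in young cells included Il33 (0.56), Usp18 (0.83), Gsta4 (0.53), Krt6a (0.81) and Thy1 (0.60), and Il33 was rhythmic in aged cells too (0.36).

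In the fit of a 24 h cosine alone, no single gene's rhythm was shown to differ between young and aged cells. The smallest p values, none past the threshold, belonged to Prickle1 of planar cell polarity (peak ZT1.45 in young and ZT8.00 in aged, adjusted p = 0.0971), Dlc1 (ZT14.09 and ZT2.75, 0.121), Dapk2 (ZT12.01 and ZT3.59, 0.131), the activin inhibitor Fst (ZT12.48 and ZT1.45, 0.131) and the hypoxia factor Epas1 (ZT13.08 and ZT6.92, 0.131). Of the 700 genes past the threshold in young cells alone, 199 had an unadjusted p under 0.05 in aged cells. The test of the difference by limma gave 0 genes, with 982 at an unadjusted p under 0.05, 4 with array weights and 332 with time as a factor in place of the cosine. In a fit that added 12 h and 8 h components, chosen after seeing the data, the 24 h component differed in 43 genes. Leaving out 1 array gave 4 genes without aged ZT20 replicate 4. It gave 2 without aged ZT0 replicate 1, young ZT0 replicate 2 or young ZT12 replicate 2, and 1 without aged ZT0 replicate 2, aged ZT12 replicate 1 or young ZT12 replicate 1. On simulated data the same test found 43 of 50 genes with an amplitude of 0.6 in young alone and 25 of 50 with 0.3. The simulation held no daily courses of other shapes, which the cosine fit counts as noise. The test may thus find fewer such genes in the real data.

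The level of expression over the whole day differed between the ages in many genes. In aged cells Cadps2, which primes vesicles for release (chromosome 6, 23262773 to 23841175), was 7.06 times its level in young cells, Zmynd15 5.27 times and Rgs4, which limits G protein signalling, 3.91 times. The young mean of Cadps2, 4.04, lies near the dim limit of 3.96, so its fold is uncertain. Other Rgs4 probe sets, of lower mean, rose by 2.75 and 1.03 on the log2 scale, so the fold of Rgs4 depends on the probe set. The inflammatory caspases Casp1 (chromosome 9, 5298517 to 5307281) and Casp4 (chromosome 9, 5308849 to 5336791) were 3.35 and 3.01 times higher. Each of these 5 was higher in all 24 aged arrays than in any young array. The largest fall was in Ltbp1, which holds latent TGF-beta in the matrix (chromosome 17, 75005480 to 75392512): its young level was 3.18 times the aged level, and 23 young arrays lay above every aged array. Other Ltbp1 probe sets, with means of 3.71 and 3.11 under the dim limit, stood at -0.07 and -0.05 on the log2 scale.

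The changes on the log2 scale were 2.82 ± 0.10 for Cadps2, 2.40 ± 0.09 for Zmynd15, 1.97 ± 0.12 for Rgs4 and 1.59 ± 0.07 for Casp4 (SE, n = 24 each; limma, adjusted p from 5.47e-27 to 4.76e-17). Bex1 rose by 2.67 ± 0.39, from a young mean of 3.49 that lies below the dim limit of 3.96, with aged arrays spread over an SD of 1.93. Igfbp2 (1.59), Akr1c19 (1.54) and Gpnmb (1.46) followed, and the wound keratin Krt6a was 2.83 times its young level. Ltbp1 fell by 1.67 ± 0.11 (adjusted p = 6.98e-16), the neurotrophic factor Nrtn by 1.16 ± 0.09 and Itih5 by 1.01 ± 0.10, and the amino acid transporter Slc38a4 was 2.29 times higher in young cells. Il1f9 (-0.93), Nrep (-0.87), the tight junction gene Cldn7 (-0.84), Sprr1b (-0.84), Zfp296 (-0.79) and Vasn (-0.78) follow. Sprr1b did not pass with cell mixture covariates (-0.52, adjusted p = 0.106). Among clock genes Per2 rose by 0.41 ± 0.09 and Bhlhe40 by 0.22 ± 0.07 in aged cells, and Nfil3 fell by 0.27 ± 0.06.

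**Figure D4:**
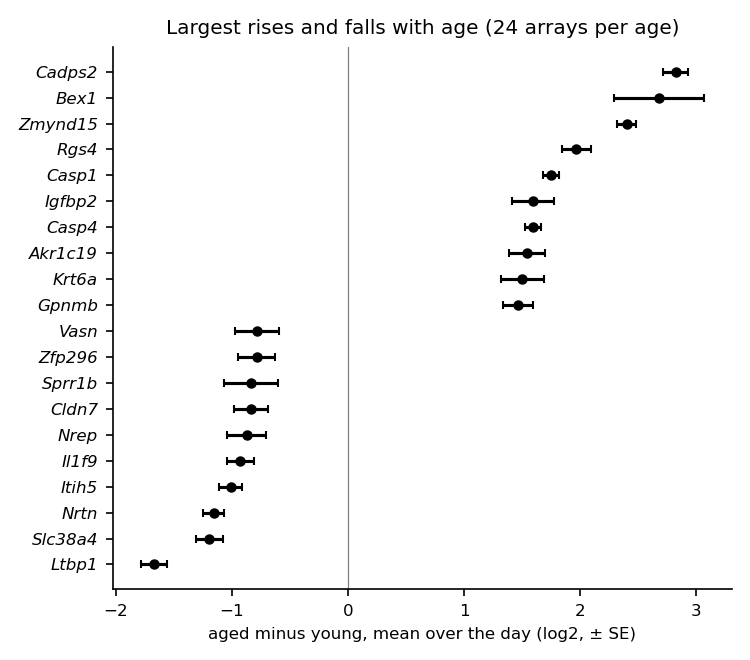
Aged minus young difference (horizontal axis, log2) of the 10 genes with the largest rise and the 10 with the largest fall; points are fitted differences and bars are 1 SE (n = 24 arrays per age). Cadps2 stands at 2.82 and Ltbp1 at -1.67.

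Many members of 3 lists, cholesterol synthesis, upper follicle and sebaceous gland, and stressed keratinocyte and inflammation, were higher in aged cells. Of 17 genes of cholesterol synthesis 11 rose and 0 fell (limma; 12 and 0 unadjusted), with Sqle at 0.89 ± 0.13, Msmo1 at 0.69 ± 0.10 and Dhcr7 at 0.38 ± 0.06 above young (log2, SE). Of 10 upper follicle and sebaceous gland markers 5 rose, led by Far2 (1.34 ± 0.15), Mgst1 (0.96 ± 0.15) and Scd1 (0.45 ± 0.07), which make or protect lipids. Of 18 genes of the stressed keratinocyte and inflammation 9 rose and 1 fell (10 and 1 with p adjusted over the list alone), among them Krt6a, the cytokine Tnf (0.74 ± 0.07), the cell cycle inhibitor Cdkn2b (0.68 ± 0.09) and Il33 (0.40 ± 0.07). The median differences of the 3 lists were 0.34, 0.29 and 0.27, and camera gave adjusted p of 9.09e-08, 6.87e-05 and 1.75e-05. With an estimated correlation none of the 3 calls held, with an adjusted p of 0.0921 for each.

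Of 14 interferon-stimulated genes 6 rose, with Usp18 at 0.84 ± 0.14, the RNA sensors Ddx58 at 0.48 ± 0.09 and Ifih1 at 0.27 ± 0.06. Of 19 immediate early genes 7 rose (9 with p adjusted over the list alone), with Egr3 at 0.84 ± 0.10, Nr4a2 at 0.52 ± 0.07 and Egr2 at 0.31 ± 0.07. Camera gave adjusted p of 0.00239 and 0.00236 for these lists, and an adjusted p of 0.448 with an estimated correlation for each. The other pathway lists did not pass camera (adjusted p from 0.0821 to 0.861). In autophagy and lysosome 5 of 22 genes fell and 1 rose (8 and 2 with p adjusted over the list alone), with Atg14 (-0.49) and Ulk1 (-0.27) of early autophagosomes. In basement membrane and adhesion Col4a2 (-0.68), Col4a1 (-0.48) and Frem2 (-0.69) fell and 1 of 17 rose, with a median of 0.0067 and a mean of -0.09. In that list 2 rose without aged ZT12 replicate 1, and 5 fell without the 4 arrays of lowest weight. In the Wnt pathway 4 of 17 rose and 2 fell, Rnf43 (-0.38) and Axin2 (-0.36). In the Notch pathway Hes1 (-0.36) and Dll1 (-0.21) fell and Jag1 rose (0.20), of 13 genes (1 rise and 6 falls with p adjusted over the list alone, and 6 falls without young ZT8 replicate 3).

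Fry, which asks whether a list moves one way without regard to other genes, passed for the 5 lists with a camera call. It also passed for bulge markers (adjusted p = 0.00174), autophagy (0.00616), basement membrane (0.0244), Notch and glycolysis (0.0321 each), T cell markers (0.0368), heat shock chaperones and Merkel cell markers (0.0407 each) and adipocyte markers (0.0415). With an estimated correlation camera called none of the 33 lists (smallest adjusted p = 0.0921, and 0.571 for autophagy).

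Among p53 targets 3 of 18 rose and 4 fell, with Plk2 (0.66) and Pmaip1 (0.58) up and the receptor Eda2r (-0.51) down, while the inhibitor Cdkn1a stood at 0.02 (adjusted p = 0.75). Of 24 S phase genes 4 rose, with Mcm4 at 0.43 ± 0.07; this count was 1 without aged ZT20 replicate 4. Of 23 G2 and mitosis genes 2 rose, with Ttk at 0.46 ± 0.11. In DNA repair 4 of 27 rose, with Nbn at 0.28, and Apex1 fell (-0.21). In glycolysis 3 of 13 rose, with the lactate exporter Slc16a3 at 0.65 and Pfkp at 0.20. Of 17 Nrf2 targets 2 rose, Srxn1 (0.85) and Gsr (0.24), and 2 fell. In the unfolded protein response 3 of 18 rose, with Xbp1 at 0.32, and Dnajb9 fell (-0.41). In heat shock chaperones 2 of 12 fell, with Bag3 at -0.38. Of 18 ribosome biogenesis genes 1 rose, and of 27 genes of oxidative phosphorylation 1 fell. Among 14 glucocorticoid-induced genes 2 rose, with Errfi1 at 0.30 and Lcn2 at 0.50, and 3 fell (2 without aged ZT12 replicate 1 and 1 without the 4 arrays of lowest weight), and among 16 clock genes 3 rose and 1 fell. With 1 array left out the falls among Nrf2 targets and heat shock chaperones and the rises among basal markers numbered 1 to 3, and the falls in oxidative phosphorylation 0 to 2.

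Markers of neighbouring cell types moved in both directions. Bulge markers of the hair follicle fell in 4 of 10 cases, with Postn (-0.76 ± 0.13), Cd200 (-0.53 ± 0.13) and Krt15 (-0.14 ± 0.03), though camera gave an adjusted p of 0.117. Of 18 suprabasal markers 4 fell, with Lor (-0.75) and Asprv1 (-0.45), and Tgm1 rose (0.47). Of 13 basal keratinocyte markers 2 rose, with Itgb4 at 0.16, and the basal factor Trp63 stood at -0.01 (adjusted p = 0.933). Of 12 T cell markers 4 rose (5 with p adjusted over the list alone), with Thy1, which other cells also express, at 0.65, and of 10 Langerhans and myeloid markers 3 rose, with H2-Eb1 at 0.53 and Cd52 at 0.18. Of 8 fibroblast markers Sparc rose (0.25), of 5 Merkel cell markers Krt8 fell (-0.32) and of 3 adipocyte markers Lpl rose (0.88). No marker of endothelium (5 measured), melanocytes (4), skeletal muscle (8) or red blood cells (3) passed in limma; 1 did at an unadjusted p under 0.05, a melanocyte marker. Camera gave none of the cell type lists but the upper follicle a call (adjusted p from 0.117 to 0.808).

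In limma 1268 genes were higher and 1119 lower in aged cells, of 12823 tested, and 3901 had an unadjusted p under 0.05. The median difference over all genes was -0.002, and -0.0264 with arrays centred on their median, where 956 genes were higher and 1454 lower, so the split between rises and falls depends on the scaling. Of the 874 genes rhythmic at either age 225 also changed in level, against 162.7 expected of independent lists. Both calls use the same arrays and the same estimate of the spread per gene. Genes with little noise pass both more easily, so the excess does not show a link of rhythm and level.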

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

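The tests of outlying arrays and of the spread, those of single arrays and technical measures for the glucocorticoid list, and those of cell admixture and technical measures for the levels were chosen after the result was seen.

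More genes were rhythmic in young than in aged cells (804 and 174). Chance can be excluded for each count: with times assigned at random within each age, only the real assignment, 1 of 100, gave as many (highest of the others 21 in young, 47 in aged and 0 for the 104 genes in both). Whether a few outlying arrays account for the gap cannot be told: without the 4 arrays of lowest weight (aged ZT12 replicate 1, young ZT0 replicates 2 and 3 and young ZT4 replicate 1) the ratio of the counts was 1.33 in place of 4.62, and 1 of 100 random removals of as many arrays per age gave a ratio as low (median 4.38), but with array weights, which count the same arrays less, it was 4.69 (1772 and 378). A wider spread between aged arrays is argued against by their residual SD, 0.931 of that of the young. An effect of age stays open: the cosine test of the difference gave 0 genes, and its 982 genes at an unadjusted p under 0.05 do not exclude chance, since 8 of 100 assignments of the ages gave as many (highest other 1362). With time as a factor, which also takes up other shapes, the course differed in 332 genes (highest other assignment 2). In the fit with added 12 h and 8 h components, chosen after seeing the data, the 24 h component differed in 43.

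The glucocorticoid list differed in its 24 h rhythm between the ages (adjusted permutation p = 0.0109), with a difference in score amplitude, aged minus young, of -0.63 ± 0.20 (SE). Each permutation p given here is of the whole 24 h rhythm, amplitude and peak time together. The amplitude difference alone was not tested. A single array as the whole cause is argued against: the difference closest to 0, with members on their original scale, was -0.5 ± 0.185, without aged ZT4 replicate 1 (permutation p = 6e-04, and at most 0.0026 without any 1 array), although adjusted over 33 lists it missed the threshold without young ZT0 replicate 3 (-0.61, 0.0759), young ZT16 replicate 1 (-0.605, 0.0528) or replicate 4 (-0.596, 0.0528), and without the 4 low-weight arrays (-0.651, 0.126), at like sizes. Background and hybridisation are argued against as the whole cause by a difference of -0.534 ± 0.192 with technical covariates (permutation p = 0.0036). Adjusted over the lists this difference no longer passed (0.109). With scores of suprabasal, fibroblast, endothelial, Langerhans and T cells the difference was -0.581 ± 0.19 (permutation p = 1e-04, the smallest these permutations can give). That argues against admixture of suprabasal cells as the whole cause. It cannot decide for the other types in that fit, whose markers were weakly expressed in young cells (median levels from 4.44 to 5.46, dim limit 3.96). With time as a factor 9 of the 14 members varied at each age and 8 differed in course, so the aged list was not flat. A difference in hormone rhythm, in stress at harvest or in sessions of collection or array preparation could give the same pattern. No measure of these is in the data. Age itself stays among the open explanations.

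Levels differed between the ages in 1268 genes that were higher and 1119 that were lower in aged cells, and chance can be excluded, since 1 of 100 assignments of the ages within each time, the real one, gave as many (highest other 1 for each). With scores of suprabasal, fibroblast, endothelial, Langerhans and T cells as covariates 84.9% of the calls stayed (follicle cells and other types were not tested). This argues against admixture of suprabasal cells as the whole cause. It cannot decide for the other types in that fit, since scores of weakly expressed markers may miss their cells. Median marker levels in young cells were 4.44 (fibroblast), 4.67 (endothelium), 5.46 (Langerhans and myeloid) and 4.49 (T cell), with a dim limit of 3.96. Background and hybridisation are argued against as the whole cause, since 76.5% of the calls stayed with technical covariates. Handling of the cells before lysis may contribute: with the immediate early gene score as a covariate 55.4% of the calls stayed, and as 7 of the 19 genes in that score rose with age, the test cannot tell handling from age. Large changes were near their size in that fit, with Casp1 at 1.83 ± 0.08 and Ltbp1 at -1.65 ± 0.13 (SE). Age stays open, and neither a difference in the source of the mice nor normalisation of the ages apart, which the sources used here do not rule out and which could shift levels, was tested.

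Dixon's ratio of gap to range was used in 168 tests, each of 1 measure in 1 group of 4 mice. It set 1 array apart in 15 tests, where chance gives 8.4. Many of the tests share mice, so they are not independent. The median of young ZT0 replicate 3 was 4.79 against 4.87 to 4.88 (gap 0.838 of the range). Hybridisation controls stood at 7.5 in aged ZT4 replicate 1 against 9.66 to 9.9 (0.899) and at 10 in aged ZT16 replicate 1 against 9.53 to 9.58 (0.897). The actin 3' minus 5' signal was apart in aged ZT4 replicate 2 (0.952) and aged ZT20 replicate 1 (0.834), and that of Gapdh in aged ZT0 replicate 2 (0.935) and young ZT0 replicate 2 (0.842). The G2 and mitosis score was 1.22 in aged ZT0 replicate 4 against 0.543 to 0.577 (0.949), and the glucocorticoid score 1.19 in young ZT16 replicate 4 against 0.988 to 1.02 (0.843). Per2 was lower than in the other mice in aged ZT0 replicate 4 (5.35, 0.899), young ZT20 replicate 2 (5.78, 0.897) and young ZT4 replicate 2 (4.97, 0.907). Arntl was 9.89 in aged ZT0 replicate 3 against 8.68 to 8.83 (0.875). Cadps2 was 3.82 in young ZT8 replicate 4 against 4.08 to 4.1 (0.931), and Casp1 was 6.64 in young ZT4 replicate 2 against 5.97 to 6.08 (0.832).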

How the results depend on the processing

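Removal of the 4 arrays of lowest weight and the technical covariates were chosen after the result was seen. With array weights 1772 genes were rhythmic in young, 378 in aged and 195 in both, and 4 differed. With time as a factor the counts were 2242, 1072, 509 and 332, a test that also takes up shapes other than a cosine. The rank test gave 304, 86 and 33 and cannot give the difference, nor can fits of each age alone. With cell mixture covariates 1154 genes were rhythmic in young, 86 in aged cells and 68 in both, and without the 4 arrays 438 in aged cells; the cause was not tested. A change of at least 1.5 times left 140 higher and 30 lower, fewer by construction. The replicate block gave 730 rhythmic genes in young and 164 in aged, 0 that differed, 1228 higher and 1079 lower. Leaving out each array gave 560 to 1188 rhythmic genes in young, 116 to 314 in aged (314 without aged ZT12 replicate 1), 79 to 134 in both, 0 to 4 that differed, 1162 to 1314 higher and 1011 to 1305 lower. The other settings gave counts within 1.5 times. Of the 94 named genes called by level, 17 lost the call in at least 1 setting and 8 with 1 array left out. Of 43 called rhythmic in young, 11 and 9 did, and of 23 in aged, 7 and 4. The 1 reversal was Sod1, -0.114 by its brightest probe set and 0.084 by the mean of all. Its other probe set, of lower mean, moved the other way (0.282, limma, unadjusted p = 0.0661). The 5 list levels called by camera kept the call in the other settings but lost it with an estimated correlation (adjusted p from 0.0921 to 0.448), and lists were not run with array weights, eBayes with trend or time as a factor. Of 6 list scores rhythmic in young, 2 lost the call in at least 1 setting and 1 with 1 array left out. Of 4 list scores rhythmic in aged cells, 2 and 1 did. Over 57 alternatives the glucocorticoid difference in score amplitude lay between -0.705 and -0.51 (members rescaled in each). The permutation test of the whole 24 h rhythm passed in 51 (adjusted p from 0.0028 to 0.126). The young mean of Bex1, 3.49, lies under the dim limit of 3.96, so its fold is less certain.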

Other observations

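The tests of a 12 h pattern and the bound used in the test of level by time of day were chosen after the result was seen, as were the genes named in the next paragraph.

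With time as a factor, the shape of the daily course differed between young and aged cells in 332 genes, and chance can be excluded, since 1 of 100 assignments of the ages, the real one, gave as many (highest other 2). Of the 14 glucocorticoid-induced genes 8 were among them, including Pdk4, Tsc22d3, Fkbp5, Angptl4 and Klf9, and of 22 autophagy and lysosome genes 4. Pdk4 stood at 4.81 at ZT0 and 7.92 at ZT16 in young cells, and at 7.06 at ZT4 and 5.63 at ZT8 in aged cells (log2 means, n = 4). The smallest p values belonged to Ppp1r10, a regulator of protein phosphatase 1 (adjusted p = 2.47e-06), and Polg2, a subunit of the mitochondrial DNA polymerase (3.49e-06). Ppp1r10 was at 8.51 ± 0.20 at ZT8 and 8.29 ± 0.22 at ZT20 in young cells, and at 9.62 ± 0.27 and 9.28 ± 0.26 in aged cells (SD, n = 4). At ZT4 it was higher in young (8.92 ± 0.27) than in aged cells (8.30 ± 0.06). Polg2 was at 6.39 and 6.41 in young and 7.57 and 7.39 in aged cells at ZT8 and ZT20, with the same order for Apol8 (5.54 and 5.72 against 7.51 and 7.55). Of the 332 genes 115 also differed in level, against 61.8 expected of independent lists. Both calls use the same arrays, and genes with little noise pass both more easily, so the excess does not show a link.

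In Ppp1r10, Polg2 and Apol8 the aged values were higher at both ZT8 and ZT20, times 12 h apart. A hypothesis is thus that the ages differ in a 12 h component. In a fit with 24 h, 12 h and 8 h components per age, the 12 h component differed in 308 genes, the 24 h component in 43 and the 8 h component in 0, by limma. The 12 h component passed in 618 genes of the young and 820 of the aged, and the 24 h component in 1224 and 394. Of the 332 genes 196 differed in the 12 h component, which held a median 59.0% of their difference against 41.8% over all genes. The test that called the 332 genes takes up a 12 h difference too, so their larger share is partly built in. For the 308, 1 of 100 assignments of the ages, the real one, gave as many (highest other 1). The 12 h component is part of the course tested with time as a factor, and the hypothesis came from genes that this test called. The 308 are thus not evidence independent of the 332. Mice collected or arrays prepared in shared sessions 12 h apart could give such a pattern as well as biology; sessions are not given in the sources used here, so no explanation was tested.

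Casp1 and Casp4, which rose together, are neighbours on chromosome 9, so it was asked whether genes that rose lie beside each other. Among 12803 placed genes 168 neighbouring pairs both rose, against a median of 124 in 10000 random assignments (highest 163; permutation p = 1e-04, the smallest these can give). Of these, 148 pairs did not share the start of their names (median of random assignments 119, permutation p = 0.0031). Shared control of neighbouring genes may contribute, as may stretches of chromosome that differ between the mice of each age; the test does not separate them.

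Whether the genes called by level differ more at some times of day was not decided: their score differed by 0.747 at ZT20 to 1.23 at ZT4 (permutation p of age by time = 0.241). The bound that would have ruled it out was reworded once this value was known; by the first wording it would have been ruled out.

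Of 16139 probe sets without a single gene name, 9533 lay above the dim limit. In limma 211 were rhythmic in young, 55 in aged and 27 in both, 2 differed, 1043 were higher and 735 lower in aged cells; for the young count, 2 of 100 assignments of the times, the real one included, gave as many (highest other 239).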
